A study of Nostoc sp. PCC 7120 = FACHB-418 with 12 samples.

How the data were processed

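The series holds 12 libraries of Anabaena (Nostoc) sp. PCC 7120, 3 at each of 0, 3, 9 and 24 h after the addition of 40 µg/ml chloramphenicol. Per the labels' protocols, cultures grew at 30 °C under 75 µE of light with 10 mM NaHCO3 and air enriched with 1% CO2, RNA was extracted with hot phenol, and libraries were made from 250 ng of total RNA with a kit that depletes ribosomal RNA. Per the submitters' processing notes, reads passed through FastQC, HISAT2 and StringTie. The versions, the genome build, the annotation and the strand setting were not given in the sources used here. The authors deposited 1 table with a column per library, whose values were taken as FPKM (fragments normalized to gene length and to the mapped fragments of the library). This unit was inferred from the values, since the table states none: the column sums differ between libraries, and several exceed what TPM or CPM would allow.

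The table lists 5999 genes by protein accession and name, 285 of them by accession only. By locus tag, 5065 (84.4%) matched the reference annotation (assembly ASM970v1), which served only for symbols (755 genes), coding lengths and gene order. Of the matched genes, 5026 are annotated as protein coding and 39 as pseudogenes. Names of 57 genes stood out of step with the accession order, and values were reported under the locus tag as printed in the table. Features of tRNA and rRNA, 0 in the table, were not analysed here.

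Depth was estimated for each library from steps that made FPKM times coding length whole over 60 low genes, with a tolerance of 0.05 of a step. The largest step that did nearly as well as the best was taken. It ranged from 71.2 to 274.7 Mb of aligned bases, and 68.3% to 90% of the values used came out whole, against 6.7% to 10% for other steps. It is an estimate. The precision of each fold change was taken from the spread between libraries of the same time, pooled over the 4 times. A gene therefore has the same SE in every comparison of the main fit, and this SE does not show the spread at 1 time.

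Genes with a mean of at least 1 FPKM over the 12 libraries (5929) were tested with limma 3.58.1 (trend, two-sided moderated tests) in R 4.3.3 on log2(FPKM + 1), with all 12 libraries and the 4 times in 1 fit. The scale of the deposited values was kept. The times 3, 9 and 24 h were compared with 0 h, and the treated times with each other. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are called changed (higher, lower, rose or fell). Aliquots came from cultures grown in triplicate. Whether a replicate number marks the same culture at every time was not given in the sources used here, and the number was not used in the model. A gene called at 3 h was counted as moved back where its change from 3 to 24 h was called in the opposite direction.

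Of 30 gene lists, 24 had at least 3 tested members and were tested with camera at a preset correlation between genes of 0.01, and again with a correlation estimated for each list. Members were found by gene symbol and, for some lists, by locus tag, since the sources used here pair the genes with no product names. Lists therefore hold only genes with a symbol or a listed tag. The 72 list tests against 0 h were adjusted together. List tests between treated times were adjusted together as a separate family. Called shares of the plasmids were compared with the chromosome by Fisher's exact test, two-sided. The lists, the threshold, the rule for named genes and the tests were set before the data were examined. Exceptions are the list tests between treated times, which were not among the tests set beforehand, and the tests marked below as chosen later.

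Named genes were, for each time against 0 h, the 8 largest rises and the 8 largest falls among called genes whose 3 later values lay outside the range at 0 h and whose higher mean was at least 10 FPKM. Genes without a symbol made up at most 3 of each 8. To these were added the 2 called members of each list with the largest change, the sigma factors, and the genes rpoB, tuf, fusA, groL, dnaK, apcA, psaA, psbA, atpA, ntcA, hetR, glnA, alr1524, alr0528 and all0458. This gave 79, 80 and 78 different genes for 3, 9 and 24 h. A gene named by more than 1 part of the rule is counted once per time, and the text gives those that describe the comparisons.

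The fit was tested on simulated data in which 200 of 5929 genes were changed between 0 h and 3 h. It recovered 62 of 100 genes changed by 2 on the log2 scale and 86 of 100 changed by 3, and 10 unchanged genes were called (6.3% of the calls). The simulated noise was independent between genes, and few genes changed. The real data differ in both, so these rates need not hold for them. Alternatives covered the replicate number as a block, fits to the 2 groups compared alone, no filter and a filter at 10 FPKM, pseudocounts of 0.1 and 5, TMM-type scaling, quantile normalization, limma without the trend, and each library left out in turn. After the depths had been seen, libraries under 100 Mb were left out and log2 depth was added as a covariate. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.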

Results

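RNA was sequenced from liquid cultures of the filamentous cyanobacterium Anabaena (Nostoc) sp. PCC 7120 that had received chloramphenicol at 40 µg/ml. Chloramphenicol binds the large ribosomal subunit and blocks peptide bond formation, so the series asks how transcripts change under translation stress. Cultures in triplicate were sampled at 0, 3, 9 and 24 h of treatment, which gave 12 libraries in 4 groups of 3. The series holds no untreated culture at 3, 9 or 24 h. Effects of chloramphenicol therefore cannot be told apart from those of time in culture or handling. The deposited table lists FPKM for 5999 genes, of which 5929 had a mean of at least 1 FPKM and were tested. It holds 0 tRNA or rRNA features, and the tRNA cluster on plasmid delta that the title of the series refers to was not analysed here. The estimated depth was 188 to 275 Mb of aligned bases per library at 0 h, 86.7 to 232.5 Mb at 3 h, 71.2 to 257.3 Mb at 9 h and 234 to 275 Mb at 24 h. Levels are given as mean ± SD FPKM over n = 3 libraries. Fold changes are limma estimates ± SE on log2(FPKM + 1), which understate the change of low genes, with Benjamini-Hochberg adjusted p-values. The strand use of the authors' counting was not given in the sources used here, so values of overlapping and antisense genes are uncertain.

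After 3 h, the genes with the largest rise encoded the D1 protein of the photosystem II reaction centre, which turns over rapidly in the light. The psbA copies all3572, alr3727 and alr4592 rose from 268 ± 66.7, 399 ± 102 and 442 ± 123 FPKM to 20300 ± 7180, 25700 ± 6840 and 27300 ± 5180 FPKM. Their log2 fold changes were 6.20 ± 0.41, 6.0 ± 0.40 and 5.96 ± 0.40, each with an adjusted p of 1.3e-06. The most abundant psbA transcript at 0 h, alr4866, went the other way, from 8720 ± 2290 to 3090 ± 279 FPKM, with a log2 fold change of -1.46 ± 0.52 that missed the threshold (adjusted p = 0.053). The psbA copy alr3742 was low, at 47.6 ± 4.19 FPKM at 0 h and 75.8 ± 11.6 FPKM at 3 h (adjusted p = 0.054). Reads of near-identical psbA copies could be divided among them, and the locus tags of all3572, alr3727 and alr4592 were out of step with the accession order of the table, so the share of each copy is uncertain.

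Transcripts of the light-harvesting phycobilisome fell the most as a group at 3 h. Its 21 genes were all lower, with a median log2 fold change of -5.00 (camera adjusted p = 1.8e-19; adjusted p = 0.05 with an estimated correlation), and 21 were lower when adjusted over the list alone. The phycocyanin gene cpcA (alr0529) fell from 13900 ± 6580 to 263 ± 101 FPKM (log2 fold change -5.66 ± 0.57, adjusted p = 2.6e-05), and its neighbour alr0528 from 23700 ± 8810 to 734 ± 312 FPKM. In the same cluster, alr0534 and alr0533 had log2 fold changes of -7.18 ± 0.39 and -7.15 ± 0.63. The allophycocyanin genes apcA (alr0021) and apcB (alr0022) fell by 4.10 and 4.29 on the log2 scale. Outside the phycobilisome, all0393 went from 467 ± 104 FPKM at 0 h to a mean of 1.00 FPKM at 3 h, where 2 of its 3 libraries listed it at 0. Its neighbour all0394 fell from 370 ± 222 to 0.721 ± 0.984 FPKM, and all3999 from 468 ± 335 to 1.62 ± 1.43 FPKM.

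The photosystem I, ATP synthase, carbon fixation and chlorophyll synthesis lists were also lower at 3 h at the preset correlation, whereas photosystem II was not. Of the 5 photosystem I genes, 4 were lower (median -2.91, adjusted p = 0.00068; adjusted p = 0.19 with an estimated correlation), and 4 were lower when adjusted over the list alone. The reaction centre genes psaA (alr5154) and psaB (alr5155) fell from 18600 ± 1620 to 1200 ± 4.08 FPKM and from 12100 ± 2680 to 922 ± 395 FPKM. The 6 ATP synthase genes were all lower, with a median of -3.08 (adjusted p = 2.9e-05; adjusted p = 0.2 with an estimated correlation), and 6 were lower when adjusted over the list alone. Among them, atpA (all0005) and atpD (all5039) each had a log2 fold change of -3.29. The 3 carbon fixation genes alr1524, rcbX (alr1525) and alr1526 had log2 fold changes of -3.13 ± 0.31, -3.78 ± 0.39 and -4.45 ± 0.54 (list adjusted p = 0.0013; adjusted p = 0.14 with an estimated correlation). Of 15 chlorophyll and heme synthesis genes, 9 were lower over all genes and 11 when adjusted over the list alone (adjusted p = 0.0013; adjusted p = 0.21 with an estimated correlation), with acsF (alr3300) at -4.11 ± 0.42 and hemE (all3909) at -2.42 ± 0.27. The chlorophyll synthesis gene bchB (alr3441), which lay outside that list, fell from 1270 ± 123 to 47.9 ± 16.8 FPKM. The 19 photosystem II genes had 4 higher and 4 lower members, or 5 and 7 when adjusted over the list alone, and no shared direction (adjusted p = 0.86; adjusted p = 0.95 with an estimated correlation). The higher members over all genes were the psbA copies all3572, alr3727 and alr4592, and psb30 (asl5128).

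Genes of the translation apparatus went in both directions at 3 h. Of 50 ribosomal protein genes, 24 were higher and 2 lower over all genes, and 25 were higher and 7 lower when adjusted over the list alone. Their median log2 fold change was 0.88 (adjusted p = 3.1e-07; adjusted p = 0.31 with an estimated correlation). The genes rplB (all4212) and rplC (all4215) rose from 800 ± 208 to 4340 ± 194 FPKM and from 494 ± 48 to 2710 ± 563 FPKM, with log2 fold changes of 2.47 ± 0.44 and 2.44 ± 0.29. Aminoacyl-tRNA synthetase genes, which charge tRNAs, had 0 higher and 9 lower of 17 members, or 11 lower when adjusted over the list alone (median -1.14, adjusted p = 0.0021; adjusted p = 0.49 with an estimated correlation). Of these, lysS (all4071) fell by 1.80 and trpS (all1269) by 1.75 on the log2 scale. The translation factors frr (alr1208) and prfC (all4379) fell by 1.74 and 1.24, whereas tuf (all4337) and fusA (all4338) had log2 fold changes of -0.78 (adjusted p = 0.061) and -0.69 (adjusted p = 0.082). The 13 translation factors had 0 higher and 3 lower members, or 1 and 4 when adjusted over the list alone (adjusted p = 0.42; adjusted p = 0.75 with an estimated correlation). The 24 genes of ribosome assembly, hibernation and rescue had 1 higher and 6 lower members, or 3 and 6 when adjusted over the list alone (adjusted p = 0.88; adjusted p = 0.95 with an estimated correlation). In that list, the plasmid gene rsgA (alr8077) rose from 38.7 ± 8.37 to 683 ± 465 FPKM (log2 fold change 3.93 ± 1.00), and hflX (all3862) fell from 381 ± 48.5 to 79.3 ± 28 FPKM (-2.29 ± 0.33).

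Heat shock genes were mostly lower at 3 h. Of 14 chaperone genes, 1 was higher and 11 lower, the same numbers as when adjusted over the list alone (median -1.78, adjusted p = 0.0024; adjusted p = 0.39 with an estimated correlation). The genes htpG (alr2323), groL (alr3662), groL (alr1896) and dnaK (alr1742) fell by 4.13, 3.38, 1.87 and 2.56 on the log2 scale, whereas dnaK (alr2446) was at 44.5 ± 7.04 and 51.1 ± 13.7 FPKM (log2 fold change 0.17, adjusted p = 0.73). The thioredoxin reductase gene trxB (all0737) rose from 196 ± 29.4 to 1910 ± 466 FPKM (3.26 ± 0.35). The sigma factor alr3280 rose from 165 ± 49.7 to 751 ± 211 FPKM (2.18 ± 0.47), and the principal sigma factor gene rpoD (all5263) fell from 2110 ± 119 to 811 ± 97.9 FPKM (-1.39 ± 0.29). The nitrogen regulator ntcA (alr4392) rose by 1.44 ± 0.27, whereas glnA (alr2328) and hetR (alr2339) had log2 fold changes of -0.52 (adjusted p = 0.46) and -0.33 (adjusted p = 0.51). The nitrogenase gene nifW (all1433), low and uneven at 0 h (8.38 ± 9.21 FPKM), was listed at 0 in all 3 libraries at 3 h, and its call (adjusted p = 0.021) was lost under 6 of 21 settings. The nitrogenase gene nifK (all1440) fell from 88.7 ± 76.2 to 10.8 ± 4.63 FPKM. All 3 genes of the iron list were lower, among them all4001, from 7220 ± 4150 to 114 ± 11.6 FPKM (list adjusted p = 0.015; adjusted p = 0.16 with an estimated correlation). Another member, fldA (alr2405) at -3.73, lost its call under 4 of 23 settings, with estimates from -3.95 to -2.41. The fall of rpoB (alr1594), -1.20 ± 0.38 with an adjusted p of 0.035, lost its call with TMM-type scaling and without any 1 of the 0 h or 3 h libraries.

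In total, 535 genes were higher and 1052 lower at 3 h, of which 490 and 969 changed at least 2-fold. Higher genes made up 33.7% of the calls on the deposited scale, 45.5% with TMM-type scaling and 45.9% with quantile normalization. The median log2 fold change of all genes was -0.23 on the deposited scale and -0.03 with TMM-type scaling. Relative to the median of all genes, the phycobilisome, ATP synthase, aminoacyl-tRNA synthetase and ribosomal protein lists stood at -4.77, -2.85, -0.91 and 1.11. Genes lower at 3 h than at 0 h numbered 670 without 0 h replicate 1 and 687 without 0 h replicate 2, and genes higher at 3 h than at 0 h numbered 354 without 3 h replicate 2 and 349 without 3 h replicate 3.

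**Figure D1:**
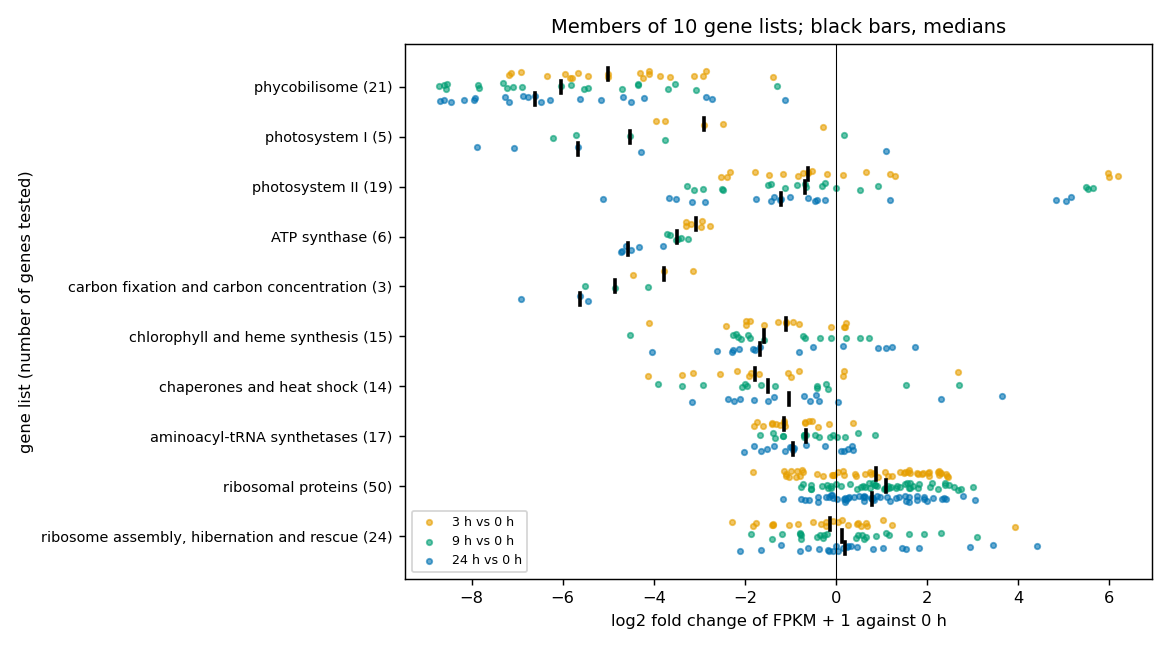
Log2 fold change of FPKM + 1 against 0 h for each tested member of 10 gene lists at 3, 9 and 24 h (points, from means over 3 libraries per time), with the median of each list as a black bar. The phycobilisome medians lie at -5.00, -6.03 and -6.61, and the ribosomal protein medians at 0.88, 1.08 and 0.78.

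At 9 h, genes of plasmid delta joined the largest rises. The plasmid gene asl8561 rose from 8.68 ± 2.92 to 2870 ± 2220 FPKM (log2 fold change 7.57 ± 0.83, adjusted p = 3.3e-05), ltrA (alr8560) from 14.9 ± 1.69 to 2470 ± 1960 FPKM (6.50 ± 0.83) and all8559, which did not match the reference and lies between delta genes by its tag number, from 9.89 ± 7.16 to 1520 ± 1450 FPKM (6.34 ± 1.09). The 3 libraries at 9 h differed widely for these genes, and asl8561 was listed at 4422, 3869 and 324 FPKM. The chromosomal gene alr1554 rose from 26.5 ± 5.55 to 3210 ± 1790 FPKM (6.68 ± 0.45). The psbA copies all3572, alr3727 and alr4592 remained high, with log2 fold changes of 5.64, 5.52 and 5.48, and trxB (all0737) reached 5240 ± 994 FPKM (4.73 ± 0.35). In contrast, psbA (alr4866) fell to 997 ± 630 FPKM (-3.27 ± 0.52, adjusted p = 5e-04).

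The phycobilisome and most photosystem I transcripts were lower at 9 h. All 21 phycobilisome genes were lower over all genes and when adjusted over the list alone (median -6.03, adjusted p = 1.1e-20; adjusted p = 0.05 with an estimated correlation). The lowest were alr0523, asr0531 and alr0524, with log2 fold changes of -8.71 ± 0.73, -8.62 ± 0.64 and -8.57 ± 0.50, and alr0523 and alr0524 were each listed at 0 in 1 library. Transcripts of cpcA (alr0529) and alr0528 were at 65.6 ± 54.9 and 81.9 ± 79.1 FPKM, and apcA (alr0021) and apcB (alr0022) at 258 ± 121 and 192 ± 103 FPKM. Levels of psaA (alr5154) and psaB (alr5155) were 249 ± 26.6 and 232 ± 67.2 FPKM, or -6.22 ± 0.31 and -5.71 ± 0.38 on the log2 scale (photosystem I list, 4 of 5 lower over all genes and when adjusted over the list alone, adjusted p = 0.00022; adjusted p = 0.16 with an estimated correlation). The 6 ATP synthase genes were lower (median -3.50, adjusted p = 1.9e-05; adjusted p = 0.19 with an estimated correlation), led by atpE (asl0009) at -3.72 and atpC (all5038) at -3.65. The 3 carbon fixation genes were lower (median -4.84, adjusted p = 7e-04; adjusted p = 0.13 with an estimated correlation), and alr1524 was at 181 ± 54 FPKM. Of 15 chlorophyll and heme synthesis genes, 0 were higher and 8 lower, or 9 lower when adjusted over the list alone (adjusted p = 0.0024; adjusted p = 0.24 with an estimated correlation). Among these, hemC (alr1878) fell by 2.26, and bchB (alr3441) outside the list fell by 5.82. The photosystem II list had 4 higher and 8 lower genes, or 4 and 9 when adjusted over the list alone (adjusted p = 0.44; adjusted p = 0.75 with an estimated correlation). All 4 higher genes were psbA copies (all3572, alr3727, alr4592 and alr3742), so no other photosystem II gene of the list was called higher.

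Of 50 ribosomal protein genes, 28 were higher and 0 lower at 9 h, or 28 and 1 when adjusted over the list alone (median 1.08, adjusted p = 1e-08; adjusted p = 0.29 with an estimated correlation). The genes rplL (alr5303) and rplJ (alr5302) rose from 321 ± 17.5 to 2670 ± 982 FPKM and from 487 ± 12.4 to 3360 ± 970 FPKM. In the ribosome assembly, hibernation and rescue list, 6 genes were higher and 2 lower, or 6 and 3 when adjusted over the list alone (adjusted p = 0.42; adjusted p = 0.75 with an estimated correlation). The gene all0458 was placed in that list by its locus tag, but its identity as a ribosome hibernation gene is doubtful. It rose from 17.3 ± 9.87 to 87.1 ± 38.8 FPKM (2.30 ± 0.48, adjusted p = 0.0031), and at 3 h it had been at 14.4 ± 6.07 FPKM. The release factor gene prfB (all0273) rose by 1.31 ± 0.33 and frr (alr1208) fell by 1.78, in a translation factor list with 1 higher and 3 lower genes over all genes and when adjusted over the list alone (adjusted p = 0.64; adjusted p = 0.86 with an estimated correlation). Of 17 aminoacyl-tRNA synthetase genes, 5 were lower over all genes and when adjusted over the list alone (adjusted p = 0.14; adjusted p = 0.75 with an estimated correlation), among them lysS (all4071) at -1.68 and hisS (all5012) at -1.38.

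Among stress and metabolic genes at 9 h, dps (all1173), whose product binds iron and DNA, rose from 160 ± 98.3 to 1290 ± 879 FPKM (2.96 ± 0.46), and the protease gene ftsH (all4776) rose from 286 ± 18.2 to 713 ± 59 FPKM (1.31 ± 0.24). The sigma factor alr3280 was at 1760 ± 1200 FPKM (3.19 ± 0.47). The chaperone list had 2 higher and 7 lower genes, or 2 and 8 when adjusted over the list alone (adjusted p = 0.035; adjusted p = 0.6 with an estimated correlation), with htpG (alr2323) at -3.90 and groES (alr3661) at -3.39. Nitrogenase genes nifK (all1440) and nifH (all1455) fell by 4.26 and 3.77, and the urea transport gene urtA (all1951) fell by 3.59. The iron list had 3 lower genes of 3 (adjusted p = 0.0087; adjusted p = 0.16 with an estimated correlation), with all4001 at -8.43 ± 0.87 and the flavodoxin gene fldA (alr2405) at -5.65 ± 1.04, or -3.94 without 9 h replicate 3, where it was listed at 4.137 FPKM against 123.5 and 249.4 FPKM in the others. Of 11 cell division and wall genes, 6 were lower over all genes and when adjusted over the list alone (median -0.91, adjusted p = 0.014; adjusted p = 0.32 with an estimated correlation), among them minE (asr3457) at -2.38 and murB (alr5066) at -2.14. The transposase gene tnpA (all3371) rose from 7.20 ± 5.41 to 52.2 ± 24.8 FPKM in a list with 2 of 6 genes higher, or 4 when adjusted over the list alone (adjusted p = 0.035; adjusted p = 0.32 with an estimated correlation). The other called gene, tnpA (alr7086) with a log2 fold change of 0.87, lost its call under 11 of 23 settings. In total, 784 genes were higher and 1140 lower at 9 h, of which 709 and 1060 changed at least 2-fold, and the median of all genes was -0.14. Higher genes made up 40.7% of these calls, 48.6% with TMM-type scaling (999 higher and 1056 lower) and 49.6% with quantile normalization (1082 and 1101).

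At 24 h, the largest rises included genes of plasmid delta, with all8559 placed there by its tag number alone. The genes asl8561, all8559, ltrA (alr8560) and alr8562 reached 11700 ± 6190, 6230 ± 1960, 11500 ± 5430 and 7930 ± 4280 FPKM. Their log2 fold changes were 10.09 ± 0.83, 9.45 ± 1.09, 9.35 ± 0.83 and 8.62 ± 0.92, with adjusted p-values of 1.9e-06, 2.7e-05, 3.4e-06 and 1.5e-05. On the chromosome, the trehalose synthesis gene treZ (all0168) rose from 10.9 ± 0.716 to 1070 ± 522 FPKM (6.39 ± 0.43), and trxB (all0737) reached 11400 ± 4840 FPKM (5.79 ± 0.35). The psbA copies alr4592, alr3727 and all3572 stood at log2 fold changes of 5.16, 5.04 and 4.84, and psbA (alr4866) fell to 285 ± 176 FPKM (-5.12 ± 0.52).

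At 24 h, levels of psaA (alr5154) and psaB (alr5155) were 83.2 ± 36.7 and 91.7 ± 35.3 FPKM (-7.87 ± 0.31 and -7.06 ± 0.38), and 4 of 5 photosystem I genes were lower, or 4 lower and 1 higher when adjusted over the list alone (median -5.65, adjusted p = 0.00072; adjusted p = 0.19 with an estimated correlation). All 6 ATP synthase genes were lower (median -4.56, adjusted p = 1.3e-05; adjusted p = 0.19 with an estimated correlation), with atpC (all5038) at -4.72 and atpE (asl0009) at -4.70. The 21 phycobilisome genes were all lower over all genes and when adjusted over the list alone (median -6.61, adjusted p = 6.3e-18; adjusted p = 0.05 with an estimated correlation). The lowest were asr0531, alr0524 and alr0528 at -8.69 ± 0.64, -8.60 ± 0.50 and -8.46 ± 0.71, and cpcA (alr0529) and apcA (alr0021) were at -7.95 ± 0.57 and -7.27 ± 0.43. The 3 carbon fixation genes were lower (median -5.61, adjusted p = 0.00072; adjusted p = 0.13 with an estimated correlation), and rcbX (alr1525) fell from 4680 ± 952 to 39.9 ± 17 FPKM. Of 19 photosystem II genes, 10 were lower and 4 higher over all genes and when adjusted over the list alone (adjusted p = 0.11; adjusted p = 0.5 with an estimated correlation). The 4 higher genes were again the psbA copies all3572, alr3727, alr4592 and alr3742. The chlorophyll and heme list had 3 higher and 9 lower genes over all genes and when adjusted over the list alone (adjusted p = 0.04; adjusted p = 0.39 with an estimated correlation), with acsF (alr3300) at -4.05 and hemF (all0650) at -2.61. The cytochrome genes petC (all2453) and petA (all2452) fell by 2.36 and 2.31.

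Of 50 ribosomal protein genes, 19 were higher and 2 lower at 24 h over all genes and when adjusted over the list alone (median 0.78, adjusted p = 0.00035; adjusted p = 0.49 with an estimated correlation). The genes rplL (alr5303) and rplA (alr5301) had log2 fold changes of 3.06 ± 0.34 and 2.78 ± 0.31, and rplA rose from 1670 ± 298 to 11400 ± 857 FPKM. The gene all0458, whose identity is doubtful, reached 374 ± 135 FPKM (4.42 ± 0.48, adjusted p = 1.7e-05). With it counted, the ribosome assembly, hibernation and rescue list had 7 higher and 3 lower genes over all genes and when adjusted over the list alone (adjusted p = 0.35; adjusted p = 0.75 with an estimated correlation). The translation factor genes frr (alr1208) and efp (all5058) fell by 3.09 and 2.29, and tuf (all4337) had a log2 fold change of -0.67 (adjusted p = 0.074). That list of 13 had 0 higher and 5 lower genes over all genes and when adjusted over the list alone (adjusted p = 0.26; adjusted p = 0.72 with an estimated correlation). Of 17 aminoacyl-tRNA synthetase genes, 9 were lower, or 10 when adjusted over the list alone (median -0.94, adjusted p = 0.037; adjusted p = 0.67 with an estimated correlation). The RNA polymerase gene rpoB (alr1594) fell from 998 ± 61.3 to 196 ± 19.7 FPKM (-2.35 ± 0.38).

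Single regulatory and stress genes went in both directions at 24 h. The gene dps (all1173) reached 4250 ± 656 FPKM (4.87 ± 0.46), and grpE (all4144) rose from 71.3 ± 19 to 988 ± 600 FPKM (3.65 ± 0.53), whereas htpG (alr2323) remained lower at -3.15 ± 0.41. The chaperone list had 2 higher and 7 lower genes over all genes and when adjusted over the list alone (adjusted p = 0.1; adjusted p = 0.69 with an estimated correlation). Among the sigma factors, alr3280 was at 1330 ± 252 FPKM (3.02 ± 0.47), alr0277 fell by 2.38 and rpoD (all5263) by 1.26. The heterocyst gene hetZ (alr0099) fell from 469 ± 248 to 21.2 ± 6.35 FPKM (-4.27 ± 0.58) and hetR (alr2339) from 756 ± 16.6 to 297 ± 113 FPKM (-1.43 ± 0.34). In contrast, nifH (alr0874) rose from 4.13 ± 4.04 to 70.6 ± 59.6 FPKM (3.87 ± 0.75). The nitrogen assimilation gene alr0608 fell by 5.50 and urtA (all1951) fell by 4.40, whereas ntcA (alr4392) and glnA (alr2328) had log2 fold changes of -0.13 (adjusted p = 0.74) and -1.14 (adjusted p = 0.072). The iron list had 3 lower genes of 3 (adjusted p = 0.015; adjusted p = 0.16 with an estimated correlation). Of the cell division and wall list of 11, 6 genes were lower, or 8 when adjusted over the list alone (adjusted p = 0.0098; adjusted p = 0.32 with an estimated correlation), among them murA (all0174) at -2.59. The transposase genes tnpA (all3371) and tnpA (alr7149) rose by 3.57 and 2.30, with 4 of 6 genes higher over all genes and when adjusted over the list alone (adjusted p = 0.045; adjusted p = 0.32 with an estimated correlation). In total, 1223 genes were higher and 1296 lower at 24 h, 1125 and 1188 of them at least 2-fold, with a median of -0.05 over all genes. Higher genes were 48.6% of these calls, 51.6% with TMM-type scaling and 49.3% with quantile normalization.

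**Figure D2:**
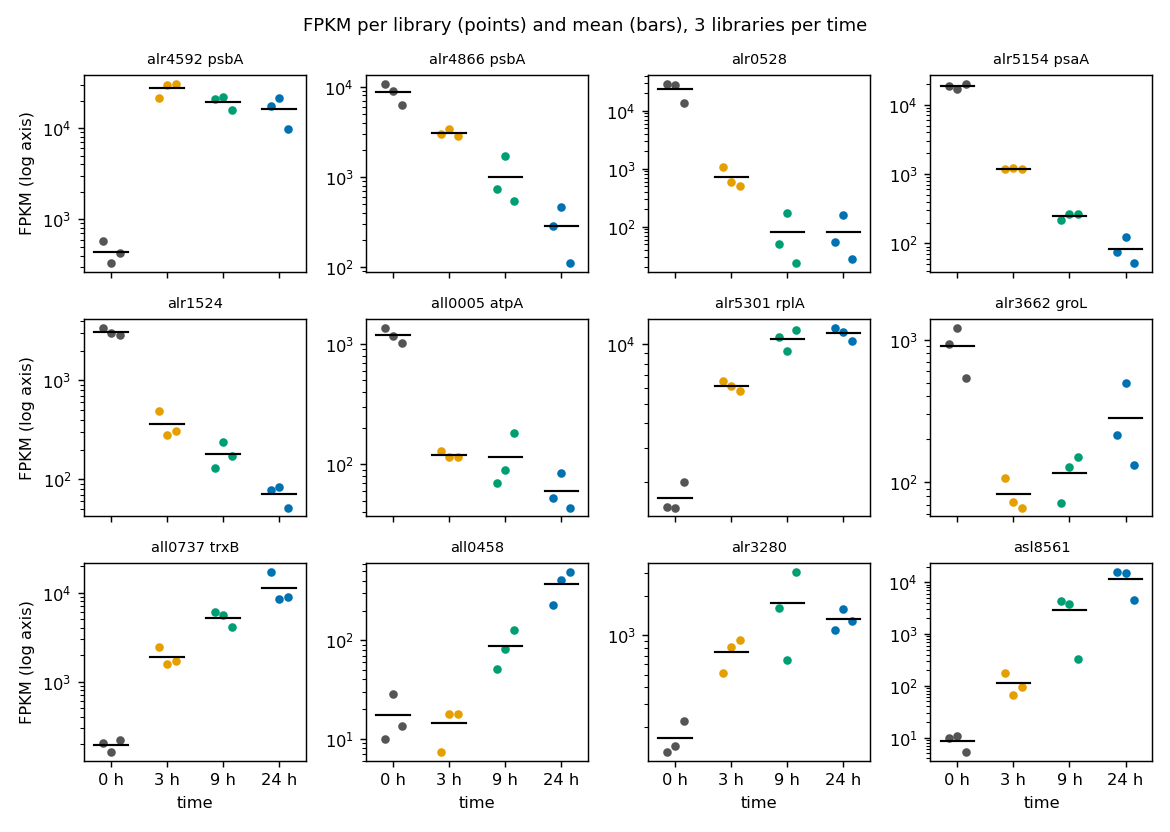
FPKM on a log axis at 0, 3, 9 and 24 h for 12 named genes, with a point per library and a bar at the mean of the 3 libraries. The level of psaA (alr5154) drops from a mean of 18600 FPKM at 0 h to 83.2 FPKM at 24 h, whereas asl8561 climbs from 8.68 to 11700 FPKM, with its libraries at 9 h spread from 324 to 4422 FPKM.

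Values of the remaining lists are given in the order 3, 9 and 24 h. The sulfur assimilation gene cysH (all4464) had log2 fold changes of -4.62, -4.91 and -5.02, in an amino acid synthesis list of 54 with 3, 5 and 8 higher and 13, 13 and 19 lower genes (3, 6 and 8 higher and 13, 13 and 19 lower when adjusted over the list alone). That list had an adjusted p of 0.034, 0.27 and 0.096, or 0.64, 0.75 and 0.71 with an estimated correlation. Of 16 nitrogen assimilation genes, 2, 2 and 2 were higher and 4, 8 and 6 lower (5, 8 and 6 lower when adjusted over the list alone). Nitrogen assimilation had an adjusted p of 0.42, 0.1 and 0.092, or 0.64, 0.31 and 0.31 with an estimated correlation. Of 30 heterocyst and nitrogen fixation genes, 2, 3 and 8 were higher and 7, 8 and 8 lower (3, 3 and 9 higher and 7, 10 and 9 lower when adjusted over the list alone). For this list the adjusted p was 0.64, 0.33 and 0.94, or 0.9, 0.75 and 0.98 with an estimated correlation. Of 12 oxidative stress defence genes, 3, 4 and 4 were higher and 4, 4 and 4 lower (5, 4 and 4 lower when adjusted over the list alone), with an adjusted p of 0.62, 0.37 and 0.57, or 0.75, 0.5 and 0.71 with an estimated correlation. Of 9 ATP-dependent and envelope protease genes, 1 was higher and 2 were lower at each time (4, 2 and 2 lower when adjusted over the list alone). Proteases as a list had an adjusted p of 0.5, 0.79 and 0.86, or 0.82, 0.95 and 0.95 with an estimated correlation.

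The DNA repair genes ruvB (all2894) and recO (alr4175) had log2 fold changes of -1.66 and 1.58 at 24 h, in a list of 15 with 1, 2 and 3 higher and 4, 2 and 1 lower genes (5, 2 and 1 lower when adjusted over the list alone). Its adjusted p was 0.64, 0.86 and 0.79, or 0.86, 0.95 and 0.94 with an estimated correlation. The phosphate transport gene pstA (all4573) had log2 fold changes of -1.90, -1.59 and -1.78. Its list of 12 had 1, 0 and 1 higher and 3, 3 and 3 lower genes over all genes and when adjusted over the list alone, with an adjusted p of 0.91, 0.86 and 0.57, or 0.95, 0.95 and 0.78 with an estimated correlation. The call of pstA at 9 h was lost without 0 h replicate 1, 0 h replicate 2 or 9 h replicate 1, with adjusted p-values of up to 0.067. In the NDH-1 list of 4, ndhD1 (alr3957) had log2 fold changes of -1.74, -1.69 and -1.86. In that list 2, 2 and 3 genes were lower (3, 2 and 3 when adjusted over the list alone), with an adjusted p of 0.1, 0.12 and 0.14, or 0.31, 0.31 and 0.32 with an estimated correlation. The cytochrome list of 13 had 1, 1 and 2 higher and 3, 3 and 3 lower genes over all genes and when adjusted over the list alone. Cytochrome genes together had an adjusted p of 0.68, 0.44 and 0.42, or 0.79, 0.69 and 0.66 with an estimated correlation. The 8 sigma factors had 1, 1 and 1 higher and 1, 0 and 3 lower genes over all genes and when adjusted over the list alone, with an adjusted p of 0.62, 0.79 and 0.64, or 0.75, 0.86 and 0.75 with an estimated correlation. At 3 h the transposase list had 1 higher gene of 6 and the cell division and wall list 5 lower of 11 over all genes and when adjusted over the list alone. Their adjusted p-values were 0.57 and 0.071, or 0.75 and 0.5 with an estimated correlation. The ATP synthase, carbon fixation and iron lists had the same counts over all genes and when adjusted over the list alone at each time. Over the 72 tests of 24 lists, 30 had an adjusted p under 0.05, and 0 did with an estimated correlation, where unadjusted p-values under 0.05 numbered 6, 5 and 5 at 3, 9 and 24 h.

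Comparing the treated times with each other asked which early changes were undone. The ribosome-associated GTPase gene hflX (all3862) stood at 381, 79.3, 232 and 522 FPKM at 0, 3, 9 and 24 h, and its rise from 3 to 24 h was 2.75 ± 0.34 on the log2 scale (adjusted p = 0.00018). The ribosome silencing factor gene rsfS (alr4169) went from 499 to 193 FPKM at 3 h and back to 503 FPKM at 24 h, obgE (alr3739) from 113 to 43.6 and 108 FPKM, and dnaK (alr1742) from 1260 to 193 and 881 FPKM. In the other direction, rpsQ (asl4206) went from 1190 to 4390 FPKM and back to 1030 FPKM, rpsH (all4202) from 538 to 2180 and 674 FPKM, and ntcA (alr4392) from 178 to 485 and 160 FPKM. The largest moves were those of all7066, from 42.6 to 929 and then 11.7 FPKM, and of all0459, from 94.5 to 31.9 and then 2350 FPKM. Apart from ntcA, hflX and dnaK, these genes were chosen after their values had been seen.

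In all, 248 of the genes called at 3 h moved back significantly by 24 h, 112 of them higher and 136 lower at 3 h. At 24 h, 202 of the 248 were not called against 0 h, 33 were still called in the 3 h direction and 13 in the other. A further 211 genes moved on in their 3 h direction, 134 of them lower. Independent lists of the same sizes would share 50.3 genes higher at 3 h and lower from 3 to 24 h (112 observed), and 162 lower at 3 h and higher from 3 to 24 h (136 observed). For genes that moved on, they would share 82.2 higher (77 observed) and 98.8 lower (134 observed). In 20 simulated data sets with no change, at most 0 genes moved back, but such data hold hardly any calls at 3 h, so this says little about the genes that did change. Both comparisons use the same 3 h libraries, so part of the 248 may come from noise in those libraries. The number of genes called at 3 h that moved back by 24 h was 144 and 145 without 0 h replicate 1 and 2, 97 and 92 without 3 h replicate 2 and 3, and 153 and 159 without 24 h replicate 1 and 3.

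Between treated times, 167 genes differed from 3 to 9 h (97 higher, 70 lower), 71 from 9 to 24 h (46 higher, 25 lower) and 1468 from 3 to 24 h (911 higher, 557 lower), and 2671 genes differed at any time. Of the 24 ribosome assembly, hibernation and rescue genes, 6 rose from 3 to 24 h and 0 fell over all genes and when adjusted over the list alone (adjusted p = 0.15; adjusted p = 0.72 with an estimated correlation). Among them, rimP (alr3828) rose from 260 to 1442 FPKM and ychF (all0723) from 64.2 to 198 FPKM, both named after their values had been seen. Ribosomal protein genes split from 3 to 24 h, with 8 higher and 9 lower, or 9 and 9 when adjusted over the list alone (adjusted p = 0.58; adjusted p = 0.92 with an estimated correlation). Genes changed between 3 h and 9 h numbered 84, 85, 26, 31, 68, 80 and 103 without 0 h replicate 1, 0 h replicate 2, 3 h replicate 2, 3 h replicate 3, 9 h replicate 3, 24 h replicate 1 and 24 h replicate 2, and 282 without 9 h replicate 2. Genes changed between 9 h and 24 h numbered 112, 7, 160, 31, 36 and 16 without 0 h replicate 3, 9 h replicates 1 and 2, and 24 h replicates 1, 2 and 3. Genes changed between 3 h and 24 h numbered 816, 813 and 943 without 3 h replicate 2, 3 h replicate 3 and 24 h replicate 1.

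The genes beside the tRNA cluster lie next to the operon named in the title of the series and do not measure its tRNAs. In the reference (assembly ASM970v1), 23 of the 70 tRNA genes form a cluster on plasmid delta between alr8563 and all8564. The gene alr8563, just before the cluster, went from 12.7 ± 6.3 to 112 ± 51.8, 1540 ± 1220 and 4530 ± 1840 FPKM at 3, 9 and 24 h. The gene all8564, just after it, went from 22.5 ± 15.2 to 102 ± 50.9, 432 ± 266 and 710 ± 146 FPKM. Both were higher than at 0 h at each time, with adjusted p-values of 0.021 and 0.019 at 3 h and 1.3e-05 and 5.5e-05 at 24 h. The 10 matched genes from all8553 to alr8563 had median log2 fold changes of 1.84, 5.50 and 7.70, with 3, 10 and 10 called higher, and all 10 were higher at 24 h than at 3 h (median 6.11). In each of them 9 h replicate 3 lay far below the other libraries at 9 h. For alr8562 the values were 2369, 2416 and 114.8 FPKM. For all8553 they were 96.51, 160 and 15.73 FPKM, the last within its range at 0 h (13.48 to 19.62 FPKM). The other 41 plasmid delta genes had medians of 0.21, 1.33 and 2.64, with 3, 17 and 35 higher and 1, 0 and 0 lower. The run was bounded after its values had been seen. Since the strand use of the counting was not given, reads of either strand may count toward these genes, asl8561 among them.

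**Figure D3:**
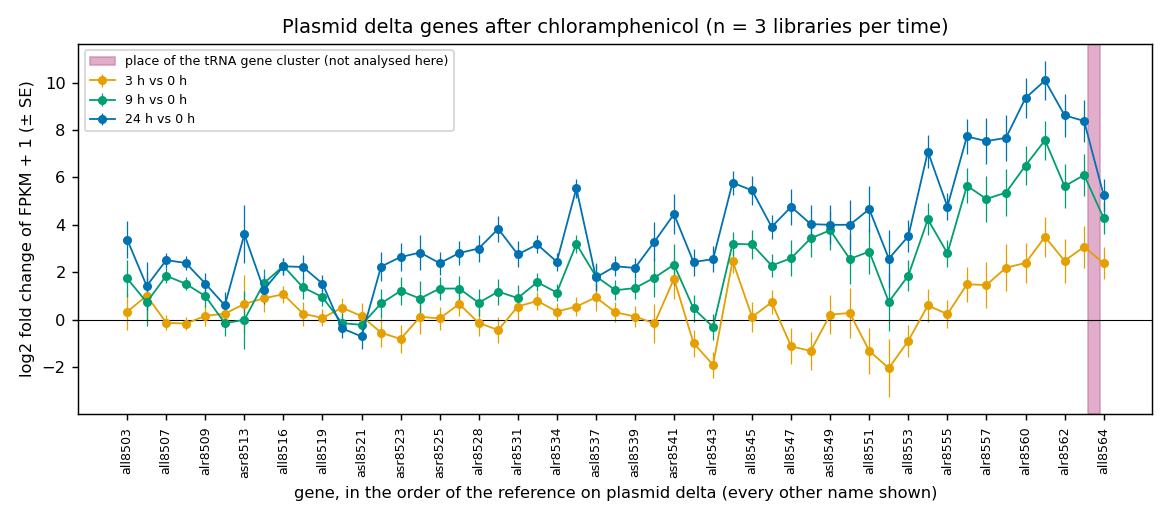
Log2 fold change of FPKM + 1 against 0 h (± SE, 3 libraries per time) for the 51 tested plasmid delta genes in the order of the reference, at 3, 9 and 24 h, with the place of the tRNA cluster shaded. The rise peaks at asl8561 with 7.57 at 9 h and 10.09 at 24 h, and is 5.25 at 24 h for all8564 after the cluster.

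The called shares differed between the replicons. By Fisher's exact test against the chromosome, 27 of 51 delta genes (52.9%) were higher at 9 h (chromosome 12.4%, adjusted p = 1e-10) and 45 of 51 (88.2%) at 24 h (chromosome 19.1%, adjusted p = 2.1e-24), and 0 were lower at 9 or 24 h. At 3 h, 6 delta genes were higher (adjusted p = 0.59). Plasmid alpha had 74 of 196 genes (37.8%) higher at 24 h (adjusted p = 3.2e-08) and 36 (18.4%) at 9 h (adjusted p = 0.043). Of the 5 plasmid zeta genes, 3, 3 and 4 were higher at 3, 9 and 24 h (adjusted p = 0.014, 0.036 and 0.014). Plasmid epsilon had 0 of 27 genes higher and 15 lower (55.6%) at 24 h (adjusted p = 0.0014). Few plasmid beta genes were lower, at 2.61%, 3.92% and 6.54% at 3, 9 and 24 h, against 19.5%, 21% and 23.6% on the chromosome (adjusted p = 9.3e-09, 3.2e-08 and 2.8e-07). Genes of 1 replicon are not independent of each other, so these p-values overstate the evidence for a replicon as a whole. Of 36 replicon tests, 18 had an adjusted p under 0.05, and 10 without 0 h replicate 2 (gene calls by replicon).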

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

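The splits of the libraries and the tests of copy number, scaling and position for the plasmid delta genes were chosen after the rise of these genes had been seen. Each result here was singled out because its effect differed between 3 h and 24 h, as tested by the direct comparison of the 2 times, except that no list test was run for the plasmid delta genes. The list tests from 3 to 24 h were not among the tests set beforehand. The photosystem I list had a median change of -2.75 from 3 to 24 h (adjusted p = 0.0015; adjusted p = 0.34 with an estimated correlation). Of its 5 genes, 4 were lower, with psaA (alr5154) at -3.92 ± 0.31, and 1 was higher, psaB (alr5314) at 1.39. The carbon fixation list had a median of -2.31 (adjusted p = 0.0057; adjusted p = 0.34 with an estimated correlation), ATP synthase -1.55 (0.0036; 0.42), phycobilisome -1.39 (0.00016; 0.36) and photosystem II -0.78 (5e-04; 0.34). With an estimated correlation none of these 5 differences passed 0.05. Within the phycobilisome, alr0524 and alr0532 had changes of -2.26 and -2.46 from 3 to 24 h, whereas alr0525 to alr0527, already low at 3 h, had 0.63, 0.79 and 0.79, with adjusted p-values of 0.26, 0.084 and 0.34.

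The plasmid delta genes from all8553 to alr8563, before the tRNA cluster, rose by a median of 6.11 from 3 to 24 h, and each of the 10 was called. Scaling of the libraries was excluded as the whole cause, since the median rise at 24 h was 7.77 with TMM-type scaling and 7.78 with quantile normalization, against 7.70 on the deposited scale. A rise in plasmid copy number may account for part of it: the other 41 delta genes had a median of 2.64 at 24 h (quartiles 2.24 and 3.91). How large that part is stays open, since the run was bounded by the values compared and no DNA was analysed here. Among the 41, all8564 beside the cluster was at 5.25. Libraries at 24 h also differed. Outside the run, alr8543 was at 82.03, 73.25 and 371.3 FPKM. In the run, alr8560 was at 14400, 14780 and 5195 FPKM, whereas all8553 was at 212.9, 180.7 and 213.7 FPKM. The rise at 24 h and the number of genes to the cluster had a Spearman rho of -0.24 over 51 delta genes. The one-sided p was 0.41 from 51 circular shifts of the gene order. The smallest p that these shifts could give was 0.02, so the test did not show a gradient toward the cluster. A weaker gradient stays open. Stretches of higher genes had medians of 2.83 (alr8522 to asl8536), 4 (all8538 to all8551) and 7.67 (all8553 to all8565) at 24 h. Among these stretches, which lie before the cluster except for the end of the last, larger medians lay closer to it. The stretches were bounded by their values, and alr8535 in the first was at 5.54. Genes listed before alr8522 lay outside them, from all8503, the first, at 3.38 to asl8521 at -0.71. A trend over the whole plasmid was therefore not shown. Transcription of the operon by its own promoter, or read-through into its neighbours, remains a hypothesis that was not tested.

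For the numbers of changed genes, each pair of times allows 10 splits of its 6 libraries into 3 and 3, too few for a share under 0.05. The real split was the 1 with the most calls each time: 1587 against 0 for the highest other split at 3 h, 1924 against 302 at 9 h, 2519 against 0 at 24 h, 167 against 1 from 3 to 9 h, 71 against 0 from 9 to 24 h and 1468 against 0 from 3 to 24 h. Of 100 splits of the 12 libraries into 4 groups of 3, the real one alone reached its 2671 genes called at any time, and the highest other gave 1095, so chance was excluded for the 4 times together. The split with 302 genes set 0 h replicates 1 and 2 and 9 h replicate 2, the deepest of those 6 libraries, against the others.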

How the results depend on the processing

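The exclusion of libraries under 100 Mb and the depth covariate were chosen after seeing the data, and the other settings were planned. Against 0 h, 176 of 198 called results of named genes kept their call under every setting that was run, and 22 lost it under at least 1, among them rpoB (alr1594) at 3 and 9 h, rsgA (alr8077) at 9 and 24 h, fldA (alr2405) and nifW (all1433) at 3 h, fusA (all4338) and sigC (all1692) at 24 h, and asl2329 at 3 and 9 h. Of the counts, 258 stayed within 1.5 times and 40 moved further. Of the list tests, 672 kept their side of the threshold, 60 were weaker and 0 changed direction. Depth was estimated at 71.2 Mb for the shallowest library, and genes near 0 FPKM are the least certain. The removal of rRNA and tRNA features was not run, since the table holds 0 of them. A setting that leaves out 1 library leaves 2 in its group and the pooled spread of the fit.

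With the replicate block, 1550 of 1587, 1876 of 1924 and 2474 of 2519 calls were shared at 3, 9 and 24 h, and genes changed between 9 h and 24 h numbered 110 in place of 71. The correlation of deviations was over 0.1 in 11 of 18 pairs with the same replicate number, from -0.26 to 0.50 (median 0.17, against -0.125 for other pairs). Pairs of replicate 3 were all over 0.1 (0.17 to 0.44), whereas those of replicates 1 and 2 went both ways, so whether the numbers mark a shared culture or handling stays open. In fits to only the 2 groups compared, genes higher at 9 h than at 0 h numbered 515, genes changed between 3 h and 9 h 13, and genes changed between 9 h and 24 h 5, whereas all calls at 3 h against 0 h, at 24 h against 0 h and from 3 to 24 h rose from 1587, 2519 and 1468 to 1712, 2640 and 1818. At 9 h against 0 h these fits called 1276 genes and shared 1267 of the 1924 calls. With TMM-type scaling, genes changed between 9 h and 24 h numbered 125. With quantile normalization they numbered 148, and genes higher at 3 h than at 0 h 816. Without the trend, genes changed between 3 h and 9 h numbered 83. Without libraries under 100 Mb, genes changed between 3 h and 9 h numbered 38 and genes called at 3 h that moved back by 24 h 142. With the depth covariate, genes changed between 3 h and 9 h numbered 372. Under that setting 1283 of 1587, 1644 of 1924 and 2519 of 2519 calls against 0 h were shared at 3, 9 and 24 h. From 3 to 24 h, 1000 of 1468 calls were shared. In the gene list tests, 30 calls became 0 with an estimated correlation. The cause was not tested for these moves unless stated.

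With 1 library left out in turn, genes higher at 3 h than at 0 h ranged from 349 to 641 and genes lower at 3 h than at 0 h from 670 to 1252. Genes changed between 3 h and 9 h ranged from 26 to 282, genes changed between 9 h and 24 h from 7 to 160 and genes changed between 3 h and 24 h from 813 to 1747. Genes called at 3 h that moved back by 24 h ranged from 92 to 331, and the replicon tests under 0.05 (gene calls by replicon) from 10 to 19. The other counts stayed within 1.5 times: genes higher at 9 h than at 0 h from 594 to 795, genes lower at 9 h than at 0 h from 762 to 1334, genes higher at 24 h than at 0 h from 953 to 1309, genes lower at 24 h than at 0 h from 998 to 1405, genes changed at any time from 1998 to 3194 and gene list tests from 26 to 31. The cause was not tested.

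Reversals concerned only results that were not called. At 3 h, dnaK (alr2446) had -0.02 without libraries under 100 Mb and -0.17 with the depth covariate, all3853 had 0.08 with TMM-type scaling, 0.41 with quantile normalization, 0.10 with a pseudocount of 5, 0.95 without libraries under 100 Mb and 1.28 with the depth covariate, and all7608 had -0.02 with a pseudocount of 5 and -0.32 with the depth covariate. At 9 h, alr2446 had 0 with quantile normalization, all3853 0.08 without libraries under 100 Mb and 0.42 with the depth covariate, and all7179 0.09 with TMM-type scaling and 0.02 with quantile normalization. At 24 h, all7608 had -0.15 with quantile normalization. With 1 library left out in turn, the values at 3 h ranged from -0.02 to 0.37 for alr2446, -0.52 to 0.20 for all0458, -0.71 to 0.95 for all3853, -0.29 to 0.25 for all7608, -0.06 to 0.82 for alr0277 and -0.15 to 0.18 for all7179. At 9 h they ranged from -0.48 to 0.01 for alr2446, -0.58 to 0.02 for dnaK (alr2990), -1.87 to 0.08 for all3853, -0.68 to 0.01 for all7608 and -0.30 to 0.16 for all7179. At 24 h they ranged from -0.01 to 0.06 for alr2990, -0.29 to 0.06 for ntcA (alr4392), -0.33 to 0.35 for all7608, -0.85 to 0.09 for sigB (all7615) and -0.29 to 0.02 for all7179. The cause was not tested.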

Other observations

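The tests in this part were chosen after the results had been seen, except the comparison of the shared axis with the time course. Several sets of neighbouring genes changed together, most of them outside the gene lists, although all0387 and all4001 belong to the iron list. The 11 genes from all0387 to alr0397 were lower at every treated time, with medians of -4.89, -4.41 and -4.60, and the 16 genes from alr3059 to alr3074 were lower at 3 h (median -3.32), of which the 8 from alr3061 to alr3068 were still lower by at least 4-fold at 24 h (median -3.62). The 8 genes from all3320 to all3327 were lower at 3 h (median -2.79), and the 7 from alr3997 to all4003, which include all4001, had medians of -5.67 and -7.09 at 3 and 9 h. In the other direction, the 5 genes from alr1537 to all1541 rose at all 3 times (medians 3.07, 2.75 and 2.99). The 6 genes from all0854 to all0859 rose at 24 h (median 4.35), where alr0857 reached 8720 FPKM from 133 FPKM at 0 h. The 5 genes from alr4525 to alr4529 rose at 3 h (median 5.08), when alr4526 rose from 61.7 to 2360 FPKM. Beside treZ (all0168), which rose to 1070 FPKM, treY (all0167) had a log2 fold change of only 1.05 at 24 h (adjusted p = 0.084), and all0164 rose from 22.3 to 2550 FPKM.

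Some of the latest rises were hardly visible at 3 h. The gene alr3090 was at 30.9, 23.9, 547 and 6072 FPKM at 0, 3, 9 and 24 h, and its neighbour asr3089 at 58.3, 85, 1280 and 6230 FPKM. On plasmid alpha, the transposase gene tnpA (alr7149) was at 26.7, 14.6, 63.7 and 139 FPKM. Among devC genes, alr4974 rose from 5.61 to 37.2 FPKM at 24 h (log2 fold change 2.62, adjusted p = 0.00079), inside a run of 7 genes from all4972 to all4978 that were all higher.

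Runs of at least 4 neighbours in the table, all called in 1 direction and changed at least 4-fold, held 103 genes in 15 runs at 3 h, 124 in 19 at 9 h and 206 in 30 at 24 h. In 1000 random gene orders the highest numbers of genes in runs were 8, 9 and 17 at 3, 9 and 24 h. Chance placement was therefore excluded for the number of genes in runs, but not for each single short run. The result is consistent with transcription in operons or over larger regions, which was not tested.

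Libraries of the same time differed from each other along 1 shared axis, which held 48.8% of the variance within times over 4960 genes with a mean of at least 10 FPKM. The scores of the 12 libraries followed log2 depth within times (Pearson r = 0.86, exact permutation p = 0.0147; Spearman rho = 0.80, exact permutation p = 0.0224; 1296 permutations within times, 1 relation tested), and r was 0.68 without the 2 libraries farthest in depth. Depth, or a property of the RNA that went with it, is therefore a candidate source. The weights of the genes on the axis followed gene length only weakly, with a Spearman rho of -0.21 across 4236 genes (interval -0.24 to -0.18). These genes are not independent replicates. The values argue against gene length as the main source, but a smaller part that goes with length stays open. Cultures at different stages of the response may also contribute: across genes, the axis had r = 0.11 with the change from 3 to 24 h, -0.16 with that from 3 to 9 h and 0.36 with that from 9 to 24 h, so this stays open. All replicate 3 libraries had negative scores (-0.36, -0.2, -0.54 and -0.23 at 0, 3, 9 and 24 h), also at 24 h, where log2 depth within the time was 0.08. A source that goes with the replicate number therefore stays open too.

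Lower calls outnumbered higher calls at 3 h, with 33.7% higher. With TMM-type scaling 45.5% were higher and with quantile normalization 45.9%, but both methods centre the libraries, which moves the share toward balance whatever the cause. Scaling as the source of the excess therefore stays open. A true shift of the total amount of mRNA cannot be told apart from scaling in values that are relative to a library total.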
